A study of Saccharomyces cerevisiae with 34 samples.

How the data were processed

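Newly made and total RNA were sequenced from cultures of the budding yeast Saccharomyces cerevisiae, laboratory strain BY4741, that were wild type (WT) or carried the KIN28 alleles kin28as or kin28is. KIN28 encodes the kinase subunit of the general transcription factor TFIIH, which phosphorylates the C-terminal domain (CTD) of RNA polymerase II, and both alleles make the kinase sensitive to added inhibitors. Per the labels, cultures received DMSO, the reversible inhibitor 1-NAPP-1 or the irreversible inhibitor CMK for 1 h, at 2 µM in the replicate 1 set and 5 µM in all later replicates. Cells were then labelled for 6 min with 5 mM 4-thiouracil (4tU), a uracil analog that enters newly made RNA and allows it to be pulled down. Cells of the fission yeast Schizosaccharomyces pombe, labelled with 4tU and not exposed to inhibitor, were added before lysis at 1 S. pombe cell to 6 S. cerevisiae cells as an external reference. Libraries were made with ScriptSeq and read as 100 bp single-end reads on a HiSeq 2000, per the labels' protocols.

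The authors deposited a table of whole-number read counts per gene for 34 libraries, 19 of pulled-down nascent RNA and 15 of total RNA, with genes of both yeasts in the same table. The submitters' processing notes name CASAVA 1.8.2, STAR 2.3.0, HTSeq 0.6.0 and the build sacCer3, without giving their roles. How reads were assigned to the 2 genomes, and whether counting used strand, is not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as the paired histone, ribosomal protein, TDH, OYE and SSA genes, are therefore uncertain for the single gene. The 10533 features were 5143 S. pombe genes, 5368 S. cerevisiae open reading frames and 22 long terminal repeat (LTR) entries, and every column matched a labelled sample. Symbols and positions came from the RefSeq annotation of the same S. cerevisiae assembly, in which 5241 open reading frames were found by systematic name and 127 were not. 102 open reading frames had 0 counts in every library.

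Library depth ran from 517887 to 15568445 reads over both species. Intervals given for shares are exact Clopper-Pearson 95% intervals and cover counting error only, because PCR copies are not independent molecules. No 2 libraries of the same group agreed within counting noise (smallest chi-square per degree of freedom 5.86), so each was counted as a separate replicate. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

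Tests of single genes used edgeR 4.0.16 in R 4.3.3 with quasi-likelihood fits (glmQLFit, glmQLFTest) to the deposited counts, after filterByExpr with a minimum count of 10, and Benjamini-Hochberg adjustment at 0.05. Library sizes were the S. pombe totals with TMM factors from S. pombe genes, so changes are per S. pombe RNA; "relative" values instead used TMM factors from S. cerevisiae genes and compare each gene with the other S. cerevisiae genes. All 6 labelled WT and kin28is groups of an RNA fraction shared a fit, with 16 nascent and 12 total libraries. The fit without a replicate term, its alternatives, the gene lists and the rule for named genes were chosen before the data were examined. Those alternatives included a replicate term (blocked fit), a fit to the 5 µM libraries alone, S. cerevisiae scaling, DESeq2 1.42.0 and leaving out each library in turn. The decision to lead with the 5 µM nascent libraries and with the blocked total RNA fit was made after the data were examined. The 5 µM fit held 10 nascent libraries and 4 residual degrees of freedom.

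The replicate number separates the 2 µM from the 5 µM libraries in the labels. In nascent RNA, 33 of 33 same-number pairs of libraries from different groups deviated together from their group means (r across genes over 0.1, lowest 0.11, median 0.46). In total RNA this held for 20 of 30 pairs (lowest r -0.16, median 0.22), and the pairing there rests on the labelled dose set. With 2 libraries per group, each value there occurs for both numbers, so the pairs are not independent.

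Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Of all combinations of list and comparison, 144 passed at the preset value and 6 with an estimated correlation, so list results describe these libraries more than they generalise. For the main list results the calls are also given after adjustment over the list alone. The named genes were KIN28, up to 6 called genes per direction (4 where groups had 2 libraries) and up to 3 members with the smallest p of each list that passed. The called genes had a mean of at least 10 counts per 1000000 S. pombe reads and no overlap between groups. The overlap condition was dropped for differences of a response between strains or RNA fractions. Because the unblocked fits called 0 genes, the same rule was applied to the blocked, the relative blocked and the 5 µM fits. Any other gene named was chosen after its values were seen.

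The ratio of S. cerevisiae to S. pombe reads per library was compared on the log2 scale with two-sided exact permutation tests. The kin28as groups and the unlabelled control had 1 library each and entered no test. For them log2 changes were taken relative to the median gene, with 0.5 added to each count. A list's median was then placed among 10000 random lists of the same size matched on expression. The tests were checked on simulated counts, drawn with no error in the S. pombe scaling and no shift between the replicate sets. The real libraries held such a shift, so the shares below do not show what the unblocked fit could find in them. For nascent kin28is CMK against DMSO, the fit to all 16 libraries without a replicate term (5209 genes) recovered 65% of genes changed 2-fold and 97% of those changed 4-fold, with 8 false calls, and the 5 µM fit (5205 genes) recovered 52% and 95%, with 9 false calls. For total RNA (5225 genes) the blocked fit recovered 69% and 98%, with 15 false calls. To follow reads in genes that are barely transcribed, the 200 S. cerevisiae genes and the 200 S. pombe genes with the fewest reads were followed in each library. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. LTR entries entered no library size or gene test, and transcripts of RNA polymerase III, snoRNA genes and mitochondrially encoded genes were not analysed here.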

Results

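The data set followed RNA synthesis and RNA levels in budding yeast after 1 h of inhibiting Kin28, the TFIIH kinase that phosphorylates the CTD of RNA polymerase II. Nascent RNA was RNA labelled for 6 min with 4tU and pulled down, and total RNA came from the same kind of cultures without the pull-down. In kin28is cells there were 3 nascent libraries with DMSO, 3 with 1-NAPP-1 and 4 with CMK, and 2 total RNA libraries per treatment. WT cells had 2 libraries per treatment and RNA fraction, kin28as cells had 1 with DMSO and 1 with 1-NAPP-1 per fraction, and a WT DMSO culture without 4tU gave 1 library per fraction. Replicate 1 received 2 µM inhibitor and later replicates 5 µM, so dose and replicate set cannot be separated. Depth was 517887 to 15568445 reads per library, and the shallowest libraries were nascent kin28is 1-NAPP-1 replicate 2 (517887 reads) and nascent WT DMSO replicate 2 (830598 reads). CPM below are counts per 1000000 S. cerevisiae reads of the library, and RPKM the same per kb of gene.

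KIN28 itself (YDL108W, chromosome IV, 267698 to 268699) was read in all 34 libraries. It stood at 28.9 to 88.9 CPM, with medians of 67.6 in 16 kin28is libraries, 55.3 in 14 WT libraries and 66.8 in 4 kin28as libraries. The alleles change the protein, so the count shows that the gene was transcribed and does not check the genotype labels.

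The first question was whether inhibition lowered RNA synthesis as a whole, read from the ratio of S. cerevisiae to S. pombe reads in nascent RNA. In kin28is cells CMK lowered the ratio against the DMSO library of the same number by 2.31-fold at 2 µM and by 2.35-fold and 3.39-fold at 5 µM. The mean paired change was -1.40 ± 0.31 on the log2 scale (SD, n = 3 pairs), a 2.64-fold fall, lower in 3 of 3 pairs. WT cells given CMK moved by 0.04 and 0.19 log2 units. The WT culture without 4tU gave a ratio of 0.144, with 12.6% S. cerevisiae reads (12.5% to 12.6%), which equals 28.0%, 28.2% and 51.9% of the ratio in the 3 CMK libraries at 5 µM. The exact paired permutation test over 3 pairs gave p = 0.25, the smallest such a design allows. Unpaired, the difference was -2.02 with exact p = 0.371, because the replicate 1 libraries had far higher ratios (5.01 log2 units with DMSO against 0.27 and 0.79 at 5 µM).

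**Figure D1:**
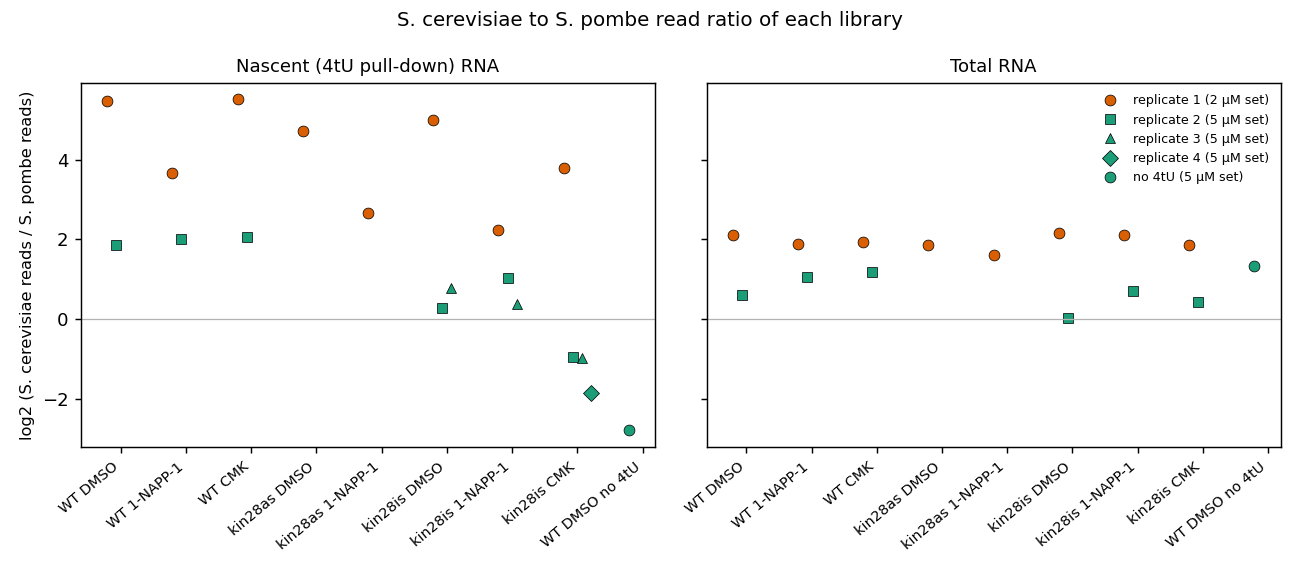
Log2 ratio of S. cerevisiae to S. pombe reads in each nascent and total RNA library, by group, with the replicate 1 (2 µM) libraries marked apart from the 5 µM libraries and the library without 4tU. Nascent kin28is CMK libraries sit at 3.80 in replicate 1 and between -1.85 and -0.96 at 5 µM, each below the DMSO library of its own number where there is one, and the library without 4tU sits at -2.80.

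Gene by gene, CMK at 5 µM lowered nascent RNA of most genes in kin28is cells. Among 5216 genes, 3743 fell (71.8%) and 12 rose, and the median gene fell 3.22-fold (3 CMK and 2 DMSO libraries). KIN28 fell by 2.19 ± 0.651 (log2 ± SE, adjusted p = 0.00271). The histone genes fell most among the fixed lists: 10 of 10 were lower, 10 also when adjusted over the list alone, with a median 7.9-fold fall (camera adjusted p = 1e-07; adjusted p = 0.67 with an estimated correlation). HTA2, an H2A gene (chromosome II, 235394 to 235792), fell by 4.45 ± 0.984 (adjusted p = 0.000128), and HTB2, an H2B gene (chromosome II, 236492 to 236887), fell by 3.43 ± 0.55 (adjusted p = 2.29e-07).

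Genes of the oxidative stress regulator Yap1 formed the next group. Of 24, 22 fell, 22 also when adjusted over the list alone, with a median 5.45-fold fall (adjusted p = 0.00018; adjusted p = 0.98 with an estimated correlation). OSI1 (YKL071W, chromosome XI, 305114 to 305884) fell by 3.91 ± 0.531 (adjusted p = 9.99e-10), the NADPH oxidoreductase gene OYE2 by 2.90 ± 0.414 (adjusted p = 6.65e-09) and the vacuolar glutathione-conjugate transporter gene YCF1 by 2.98 ± 0.438 (adjusted p = 1.91e-08). G2/M genes fell in 19 of 20 (19 adjusted over the list alone; adjusted p = 0.0061; median 4.6-fold), among them the cyclin gene CLB2 at -2.82 ± 0.59 and the transcription factor gene SWI5 at -2.76 ± 0.596. Ribosome biogenesis genes fell in 75 of 81 (76 adjusted over the list alone; adjusted p = 0.0029; median 3.66-fold), with NOP15 at -3.05 ± 0.595 and UTP20 at -2.58 ± 0.47. mRNA decay factors fell in 31 of 34 (31 adjusted over the list alone; adjusted p = 0.036; median 4.03-fold), with the 5' to 3' exonuclease gene XRN1 at -2.61 ± 0.478. For these last 3 lists the adjusted p = 0.98 with an estimated correlation. Other large falls were HPT1 (-3.85 ± 0.727), which makes a purine salvage enzyme, the RNA polymerase III subunit gene RPC25 (-3.80 ± 0.678) and THO1 (-3.54 ± 0.715).

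Ribosomal protein genes fell less than most. 52 of 132 were lower (29 adjusted over the list alone), their median fall was 2.08-fold, and relative to the other S. cerevisiae genes their median turned to 0.58 (adjusted p = 0.0016; adjusted p = 0.98 with an estimated correlation). The paralog pair member RPL31B was among the exceptions at -2.95 ± 0.606. Of the phosphate starvation genes of Pho4, 9 of 17 fell and 1 rose (adjusted p = 0.00071; adjusted p = 0.98 with an estimated correlation; relative median 0.16), including PHO86 at -2.51 and VTC1 at -2.27, while the glycerophosphoinositol transporter gene GIT1 rose by 2.07 ± 0.922. Of the 4 alpha-specific mating genes 1 fell (0 adjusted over the list alone; median -0.32, relative median 1.33; adjusted p = 0.0029; adjusted p = 0.56 with an estimated correlation). Among the 3 marker loci of the strain background URA3 was called higher (4.89 ± 1.09, adjusted p = 0.00014) on 1 library, standing at 359 CPM in CMK replicate 2, 10.5 and 2.89 in CMK replicates 3 and 4, 2.72 and 0 with DMSO and 355 in the library without 4tU. The largest rises under the naming rule were CMC1 (3.42 ± 0.534), RHO2 (2.77 ± 0.515), SPR3 (2.57 ± 1.18) and MLS1 (2.50 ± 1.03). GIT1 stood at 94.1 to 133 CPM in the CMK libraries and 108 without 4tU, and SPR3 at 34.7 to 52.6 and 101. The alpha-specific and marker lists were not separated from the background in the least-read genes, given below.

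The remaining lists did not stand apart from other genes in camera, and most members of each fell, except for the methionine genes. Lower were 10 of 11 genes of Kin28 and TFIIH (adjusted p = 0.94), 10 of 12 other CTD kinases and Mediator kinase module genes (0.76), 12 of 12 RNA polymerase II subunits (0.21), 21 of 31 stress-induced genes of Msn2/4 and Hsf1 (0.51), 10 of 12 pleiotropic drug resistance genes (0.72), 24 of 34 G1/S genes (0.67) and 12 of 15 M/G1 genes (0.23). Relative to other S. cerevisiae genes the median turned above 0 for Kin28 and TFIIH (0.22), stress-induced (0.20) and G1/S genes (0.21). In metabolism 16 of 18 glycolysis, 28 of 43 TCA cycle, 36 of 43 Gcn4 amino acid, 10 of 21 methionine, 19 of 25 ergosterol and 9 of 14 pyrimidine genes were lower, as were 5 of 6 a-specific and 5 of 6 haploid-specific genes, and the relative median turned above 0 for TCA cycle (0.08), methionine (0.45), ergosterol (0.14), a-specific (0.17) and haploid-specific genes (0.20). Adjusted over the list alone the numbers were 11 for other CTD kinases, 23 for G1/S, 38 for Gcn4 and 9 for methionine genes and the same for the other lists of this paragraph. The 200 least-read S. cerevisiae genes stood at 9.67 to 20.7 RPKM in the CMK libraries, 2.35 and 4.41 with DMSO and 29.0 without 4tU. The fit to all 16 nascent libraries called 0 genes with edgeR (3 at unadjusted p under 0.05; DESeq2 called 0), and with the replicate term it called 1, HHT1. Scaling to S. cerevisiae genes called 0 with all 16 libraries and gave 125 higher and 107 lower in the 5 µM set. The S. pombe-scaled 5 µM count fell most without DMSO replicate 3, which left 1 DMSO library.

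CMK and 1-NAPP-1 differed in nascent RNA of kin28is cells at a matched dose of 5 µM. With CMK 3901 of 5216 genes were lower than with 1-NAPP-1 (74.8%) and 1 was higher, and the median gene was 3.6-fold lower (3 CMK and 2 1-NAPP-1 libraries). Histone genes were lower in 10 of 10, by a median 10.4-fold (adjusted p = 1.2e-14; adjusted p = 0.27 with an estimated correlation). Yap1 genes were lower in 22 of 24 (adjusted p = 0.00026; adjusted p = 0.98 with an estimated correlation), led by OSI1 at -3.98 ± 0.534 (adjusted p = 7.48e-11). G2/M genes were lower in 20 of 20 (adjusted p = 0.0037), decay factors in 34 of 34 (0.01) and ribosome biogenesis genes in 77 of 81 (78 adjusted over the list alone; 0.0015). For the other lists named so far the counts over the list alone were equal. Ribosomal protein genes were lower in 57 of 132 (40 over the list alone) and stood above other genes, with a relative median of 0.56 (adjusted p = 0.00026), as did methionine genes (9 of 21 lower, 8 over the list alone; 0.027) and Pho4 genes (9 of 17, 8; 0.00077). For these 6 lists adjusted p = 0.98 with an estimated correlation. Alpha-specific genes (1 of 4 lower; 0.00026) and the marker loci (0 of 3; 0.00045) stood above other genes too, with adjusted p = 0.27 with an estimated correlation. The least-read S. cerevisiae genes stood at 9.67 to 20.7 RPKM with CMK and at 4.91 and 4.36 with 1-NAPP-1. The alpha-specific and marker lists were not separated from that background. Under the naming rule the largest differences were in PMP3, a small plasma membrane protein gene (-5.78 ± 0.978), and STF2 (-5.44 ± 1.55). HHT1 differed by more (-10.8 ± 0.685) and rested on 1-NAPP-1 replicate 2, at 6019 CPM against 7.27 in replicate 3. KIN28 differed by -2.42 ± 0.674 (adjusted p = 0.00116). At 2 µM, with 1 library each, the ratio to S. pombe was 2.95-fold higher with CMK than with 1-NAPP-1, opposite to the 3.97-fold and 2.58-fold lower ratios at 5 µM. The paired mean over the 3 numbers was -0.60 ± 1.90 (SD; exact paired permutation p = 0.75, smallest possible 0.25). All 16 libraries together called 0 genes with edgeR (2 at unadjusted p under 0.05; DESeq2 0) and 1, HHT1, with the replicate term. Relative to other S. cerevisiae genes 42 were higher and 59 lower at 5 µM. The S. pombe-scaled 5 µM count fell most without 1-NAPP-1 replicate 2, which left 1 library of that treatment.

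1-NAPP-1 against DMSO in kin28is nascent RNA moved in no single direction. The ratio to S. pombe was 6.83-fold lower in the 2 µM pair, and at 5 µM it was 1.69-fold higher in replicate 2 and 1.32-fold lower in replicate 3 (paired mean -0.80 ± 1.8, SD; unpaired exact permutation p = 0.9, smallest possible 0.1). At 5 µM 7 genes rose and 0 fell with edgeR (40 at unadjusted p under 0.05), the median gene stood at 0.15, and KIN28 at 0.23 ± 0.706. The rises were in CMC1 (7.2 ± 0.658), RHO2 (7.19 ± 0.655), HHT1 (7.14 ± 0.675), ARO4 (5.61 ± 0.645), SOM1 (4.96 ± 0.966), ROF1 (3.27 ± 0.722) and EMW1 (2.46 ± 0.587). The level of RHO2 was uneven between replicates, at 15130 CPM in 1-NAPP-1 replicate 2, 151.8 in replicate 3 and 73.57 in DMSO replicate 2. Histone genes passed upward (median 0.56, 1 of 10 higher; adjusted p = 5.4e-05; adjusted p = 0.98 with an estimated correlation), and the called member, HHT1, stood at 6019 CPM in 1-NAPP-1 replicate 2 and 7.27 in replicate 3. All libraries together called 0 genes with edgeR (4 at unadjusted p under 0.05; DESeq2 0).

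WT cells served as the control without a sensitized kinase. In nascent RNA CMK left the median WT gene at 0.19 and 1-NAPP-1 at 0.22 at 5 µM, with 1 library per treatment at that dose. The ratio to S. pombe with 1-NAPP-1 was 3.5-fold lower at 2 µM and 1.11-fold higher at 5 µM, so at 2 µM it was lower in WT as well as in kin28is cells. In the same set 4 genes were lower with CMK, HHT1 (-6.44 ± 0.922), CMC1 (-5.55 ± 0.863), RHO2 (-5.15 ± 0.843) and ARO4 (-3.53 ± 0.827). The same 4 were lower with 1-NAPP-1, HHT1 (-4.98 ± 0.86), RHO2 (-4.60 ± 0.821), CMC1 (-4.48 ± 0.819) and ARO4 (-3.67 ± 0.833), and all 4 stood high in WT DMSO replicate 2 (HHT1 at 5951 and RHO2 at 3130 CPM). Histone genes as a list also stood below other WT genes with CMK (median -0.16) and with 1-NAPP-1 (median -0.32), at the preset correlation and not with an estimated one. HHT1 is on this list and was its called member. The list result was not separated from the level of HHT1 in WT DMSO replicate 2. With 1-NAPP-1 Yap1 (median -0.08, 0 of 24 called, 2 lower over the list alone; adjusted p = 0.0078), Gcn4 (0.013), decay factor (0.02) and G1/S genes (0.04) also stood below other WT genes, and Pho4 genes above them (0.012), each with adjusted p = 0.98 with an estimated correlation. Alpha-specific genes (0.012) and the marker loci (0.015) were above too, with adjusted p = 0.69 with an estimated correlation. The least-read S. cerevisiae genes stood at 16.8 RPKM in WT 1-NAPP-1 replicate 2 and 3.01 in WT DMSO replicate 2. The alpha-specific and marker lists were not separated from that background. With all libraries edgeR called 0 genes for CMK and 0 for 1-NAPP-1 (0 and 1 at unadjusted p under 0.05), and DESeq2 called 0 and 0.

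The response to CMK at 5 µM differed between kin28is and WT cells for 18 genes, with a more negative change in kin28is for 14 and a more positive one for 4. WT had 1 CMK and 1 DMSO library at that dose, the latter with 830598 reads, and was assumed to vary like the other groups. OSI1 differed by -4.77 ± 0.997 (adjusted p = 0.00219), HTB2 by -4.26 ± 1.04 (adjusted p = 0.0206), the GDP-mannose synthesis gene PSA1 by -4.17 ± 1.07 and the threonine aldolase gene GLY1 by -4.0 ± 0.982. Yap1 genes as a list differed by a median of -2.77 with 4 of 24 called (20 adjusted over the list alone; adjusted p = 0.0062; adjusted p = 0.97 with an estimated correlation). Histone genes as a list did not pass (median -2.69, 1 of 10 called, 5 lower and 1 higher over the list alone, adjusted p = 0.33). Alpha-specific genes (median -0.71) and the marker loci (median 0.234) stood above other genes at the preset correlation and not with an estimated one. These lists were not separated from the background in the least-read genes. The median gene differed by -1.91, 3.75-fold lower in kin28is, and 1737 genes had an unadjusted p under 0.05. The 4 opposite differences were in CMC1, RHO2, SOM1 and ARO4, which all stood high in WT DMSO replicate 2 (CMC1 at 2602 and SOM1 at 61.4 CPM). With the replicate term added to the 5 µM fit, OSI1 alone of the negative differences was still called (-4.55 ± 1.08), beside these 4. All libraries together called 0 (1 at unadjusted p under 0.05; DESeq2 0), and scaling to S. cerevisiae genes called 0 at 5 µM. In the S. pombe-scaled 5 µM fit the count rose without kin28is CMK replicate 4. It fell without each other kin28is CMK or DMSO library and with the replicate term.

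Without inhibitor, the nascent ratio to S. pombe was 1.39-fold lower in kin28is than in WT cells in replicate 1 and 3.02-fold lower in replicate 2. The difference did not pass (unpaired -1.65, exact permutation p = 0.5, smallest possible 0.1). Without WT DMSO replicate 1 the unpaired difference turned to 0.157, with the dose sets unbalanced between the strains. In the 5 µM set 23 genes were lower and 0 higher, and the median gene stood at -1.27, with 1 WT library. The largest, HHT1 (-8.96 ± 0.748), RHO2 (-6.75 ± 0.669) and CMC1 (-6.51 ± 0.665), are genes that stood high in WT DMSO replicate 2. HHT1 is also on the histone list below, whose result was not separated from that level. Ribosomal protein genes stood above the other genes (median -0.64, and 0.59 in relative scaling; adjusted p = 1e-07). Histone genes stood below them without any inhibitor (median -1.72, 2 of 10 called, 8 over the list alone; adjusted p = 7e-08), as did G1/S genes (median -1.72, 0 of 34 called, 17 over the list alone; adjusted p = 3.1e-05) and ribosome biogenesis genes (median -1.52; adjusted p = 0.022). For these 4 lists adjusted p = 0.98 with an estimated correlation. In total RNA 0 genes differed (edgeR, 0 at unadjusted p under 0.05; DESeq2 0). The 6 a-specific mating genes were higher as a list in kin28is total RNA (median 0.52 blocked; adjusted p = 3e-13; adjusted p = 0.26 with an estimated correlation), with 0 called singly and 0 when adjusted over the list alone. With all nascent libraries edgeR called 0 genes (5 at unadjusted p under 0.05; DESeq2 0).

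Total RNA showed which transcripts were lower after 1 h. In the blocked fit CMK lowered 106 genes and raised 16 of 5219 in kin28is cells (2 libraries per group). Yap1 genes led: 16 of 24 fell (21 adjusted over the list alone), with a median of -1.63 (adjusted p = 5.3e-21; adjusted p = 0.57 with an estimated correlation). GRE2, a methylglyoxal reductase gene (chromosome XV, 43694 to 44722), fell by 2.38 ± 0.341 (adjusted p = 1.44e-08), OSI1 by 2.28 ± 0.347 (adjusted p = 1.28e-07), the nitroreductase-like gene HBN1 by 2.21 ± 0.342 and the glutathione peroxidase gene GPX2 by 2.24 ± 0.348. GRE2 went from 2085 and 1760 CPM with DMSO to 399.2 and 399.2 with CMK. Histone genes fell in 6 of 10 (10 adjusted over the list alone; median -1.39; adjusted p = 1e-11; adjusted p = 0.57 with an estimated correlation), with HTA2 at -2.84 ± 0.742, HHF2 at -2.10 ± 0.37 and HTB2 at -1.91 ± 0.349. KIN28 stood at 0.09 ± 0.562.

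**Figure D2:**
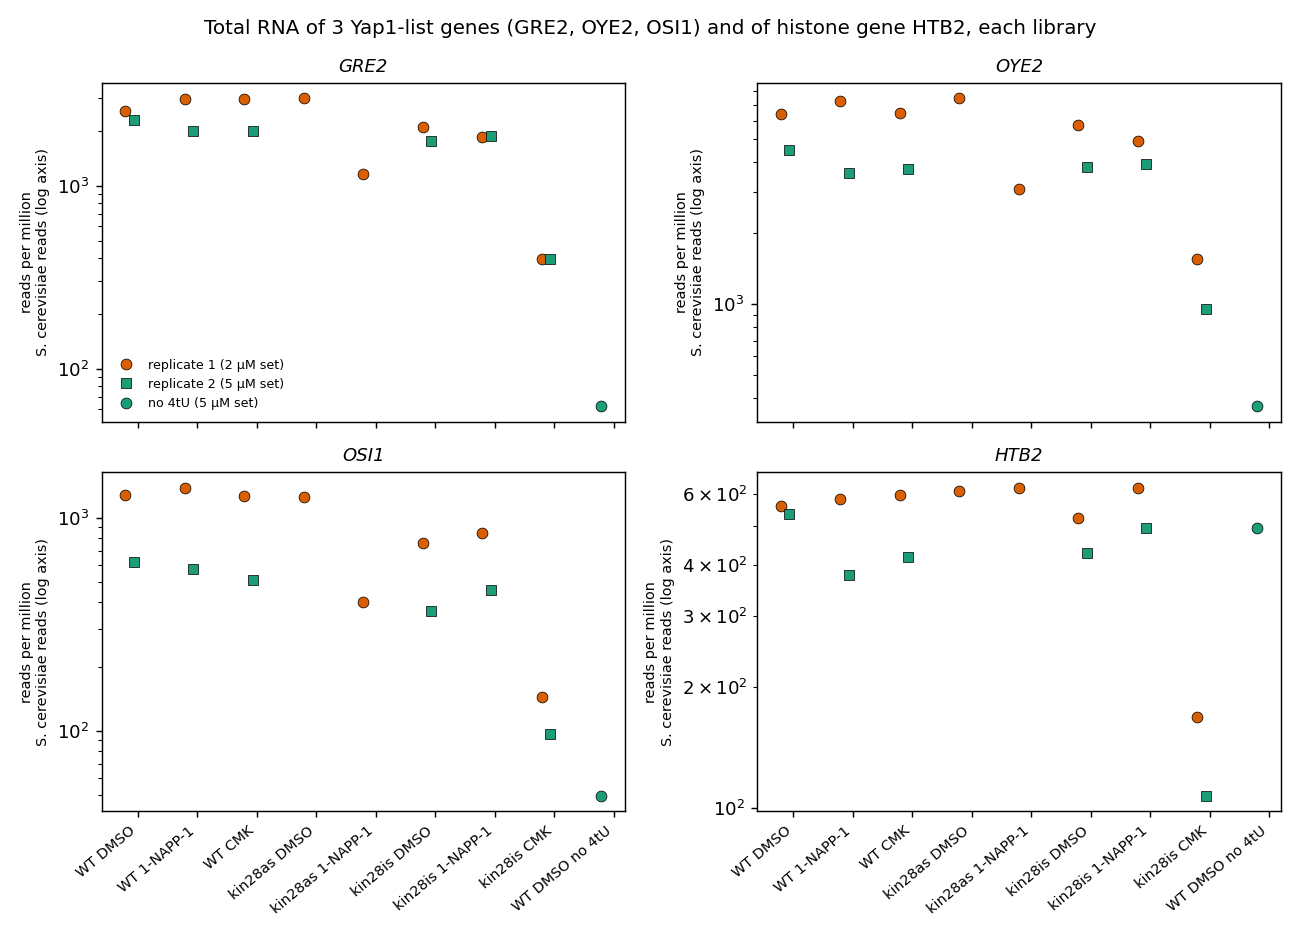
GRE2, OYE2, OSI1 and HTB2 in each total RNA library, in counts per 1000000 S. cerevisiae reads on a log axis, by group, with replicate 1 (2 µM), replicate 2 (5 µM) and the library without 4tU marked. In both kin28is CMK libraries each of the 4 genes lies below its kin28is DMSO libraries, and GRE2, OYE2 and OSI1 lie low in the library without 4tU (62.3, 368 and 49.6), where HTB2 does not.

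Smaller changes ran through other groups of total RNA in the same blocked fit, in which 106 of all 5219 genes fell. Ribosomal proteins fell in 3 of 132 (5 adjusted over the list alone; adjusted p = 3e-06), with RPL31B at -1.87 ± 0.357, and ribosome biogenesis genes in 5 of 81 (7; adjusted p = 7.2e-05), with the nucleolin-like gene NSR1 at -1.84 ± 0.352. Glycolysis genes fell in 2 of 18 (5; adjusted p = 0.00036), including the hexokinase gene HXK2 at -1.71 ± 0.335 and TDH2 at -1.26. Gcn4 amino acid genes fell in 3 of 43 (5 lower and 1 higher over the list alone; adjusted p = 0.0027), with HIS1 at -1.58 ± 0.343, and decay factors in 1 of 34 (1; adjusted p = 0.015), LSM2 at -1.70 ± 0.4. TCA cycle (adjusted p = 0.00036), RNA polymerase II subunit (0.0013) and ergosterol genes (0.007) passed downward and G1/S (0.0051) and alpha-specific genes (0.013) upward with 0 members called in each (1 polymerase and 3 alpha-specific genes over the list alone). With an estimated correlation the adjusted p was 0.88 for all lists of this paragraph so far. In the relative blocked fit, genes were also cut into 10 groups by expression. Subtracting reads spread evenly over the genome moved the median of the highest group from -0.488 to 0.0824 and of the lowest from 1.19 to 0.381. These list results were not separated from that background. Lists that did not pass were Kin28 and TFIIH (0.53), other CTD kinases (0.38), stress-induced (0.47), drug resistance (0.53), G2/M (0.38), M/G1 (0.35), methionine (0.28), Pho4 (0.35), pyrimidine (0.067), a-specific (0.38) and haploid-specific genes (0.77).

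The 16 higher genes, such as SDH9 (2.59), MRX10 (2.39), HFM1 (2.34) and YBR032W (2.25), mostly lay near the least-read genes in level. Of the 16, 13 stood under 3 times that level in a kin28is DMSO or CMK library, while YBR032W stood at 7.64 to 11.5 times. The 200 least-read S. cerevisiae genes rose along with CMK, from 10.4 to 23.2 RPKM in replicate 1 and from 3.02 to 49.2 in replicate 2, and stood at 40.1 without 4tU. The unblocked fit called 0 genes with edgeR (10 at unadjusted p under 0.05) and 0 with DESeq2. Relative scaling with the replicate term gave 964 higher and 1061 lower, among them 106 of the 106 and 16 of the 16. The fits that left out a library used S. pombe scaling and the replicate term. Without DMSO replicate 1 the balance turned, with 1607 genes higher and 99 lower (1706 in all), and without DMSO replicate 2 there were 1 higher and 334 lower, and without CMK replicates 1 and 2 the count was 49 and 16.

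**Figure D3:**
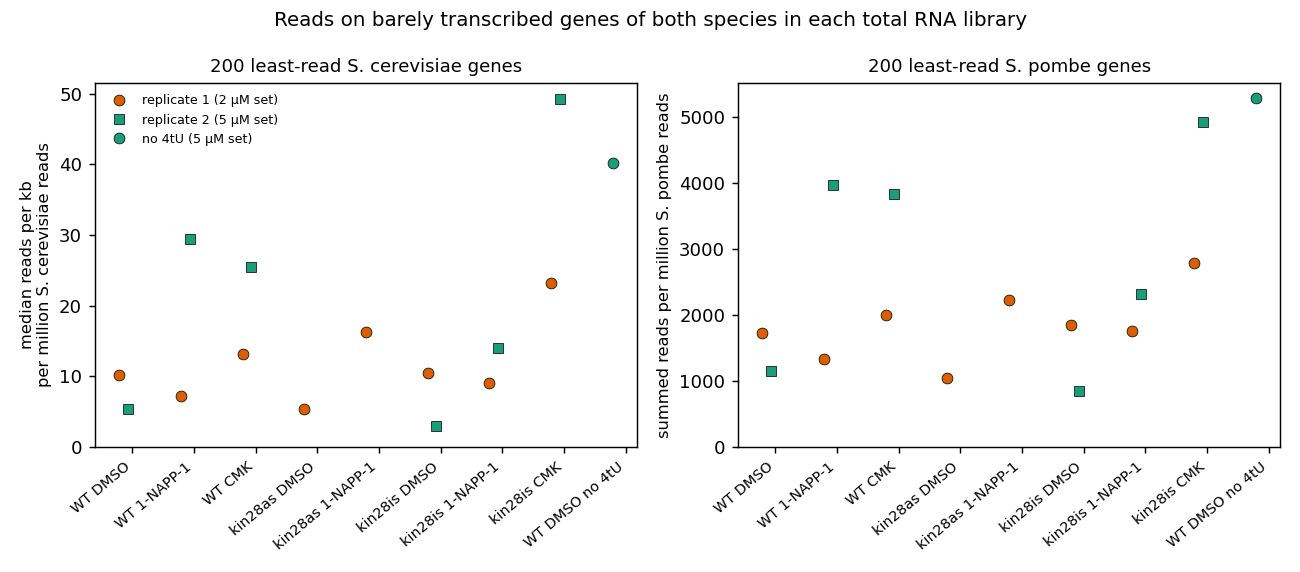
Reads in the 200 least-read S. cerevisiae genes (per kb per 1000000 S. cerevisiae reads) and the 200 least-read S. pombe genes (per 1000000 S. pombe reads) in each total RNA library, by group. In kin28is the S. cerevisiae value was 23.2 and 49.2 with CMK and 10.4 and 3.02 with DMSO, and the S. pombe genes, from cells that met no inhibitor, moved in the same direction.

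Against 1-NAPP-1 at matched doses, CMK lowered 208 of 5219 genes in kin28is total RNA and raised 0 (blocked edgeR fit, 696 at unadjusted p under 0.05; DESeq2 blocked called 422). Yap1 genes were lower in 20 of 24 (22 adjusted over the list alone; median -1.77; adjusted p = 1.8e-23; adjusted p = 0.47 with an estimated correlation), led by OSI1 (-2.74 ± 0.352, adjusted p = 3.72e-11) and GRE2 (-2.56 ± 0.342, adjusted p = 2.18e-10). Histone genes were lower in 6 of 10 (9 adjusted over the list alone; adjusted p = 1.9e-10; adjusted p = 0.47 with an estimated correlation), with HTB2 at -2.37 ± 0.354. The glycolytic genes TDH2 and ENO1 differed by -1.58 and -1.36. Glycolysis (0.0029), ribosome biogenesis (0.0029), TCA cycle (0.0021), Gcn4 (0.0073), ergosterol (0.0073), decay factor (0.014) and polymerase II subunit genes (0.0012) passed downward and G1/S (0.0073) and alpha-specific genes (0.025) upward, each with adjusted p = 0.93 with an estimated correlation. The least-read genes were also higher with CMK than with 1-NAPP-1 (23.2 against 8.99 RPKM and 49.2 against 14). These list results were not separated from that background. The ratio to S. pombe differed by -0.25 at 2 µM and -0.27 at 5 µM (exact paired permutation p = 0.5, the smallest possible). Unblocked, edgeR called 0 genes (5 at unadjusted p under 0.05) and DESeq2 called 0. Relative scaling with the replicate term gave 161 higher and 634 lower. The fits that left out a library used S. pombe scaling and the replicate term. Leaving out 1-NAPP-1 replicates 1 and 2 gave 43 and 53, and leaving out CMK replicates 1 and 2 gave 96 and 26.

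1-NAPP-1 against DMSO changed 0 genes in kin28is total RNA (edgeR, 0 at unadjusted p under 0.05, 0 with the replicate term; DESeq2 0). Ribosomal protein genes passed as a list, with a blocked median of -0.04 and -0.37 in relative scaling (adjusted p = 1.3e-49; adjusted p = 0.96 with an estimated correlation). Histone genes passed below other genes with a blocked median of 0.14 (adjusted p = 0.00041; adjusted p = 0.96 with an estimated correlation). Yap1 genes did not pass, with a blocked median of 0.22 (adjusted p = 0.12). In WT total RNA CMK changed 0 genes and 1-NAPP-1 changed 0 (edgeR, 0 and 0 at unadjusted p under 0.05; DESeq2 0 and 0). With CMK in WT, Yap1 genes had a blocked median of 0.06 and histone genes of -0.01, turning to -0.26 and -0.32 in relative scaling (adjusted p = 0.00022 and 0.00011; adjusted p = 0.99 with an estimated correlation). Ribosomal protein (2.6e-20), ribosome biogenesis (9.1e-08), glycolysis (8.4e-06), Gcn4 (3.8e-06) and TCA cycle genes (0.00011) passed below other genes in WT with CMK too, each with adjusted p = 0.99 with an estimated correlation. With 1-NAPP-1 in WT, Yap1 and histone genes passed with medians of 0.06 and 0.05 (adjusted p = 0.018 and 0.022; adjusted p = 0.95 with an estimated correlation). WT least-read genes also moved, from 5.38 RPKM with DMSO to 25.4 with CMK and 29.4 with 1-NAPP-1 in replicate 2, and from 10.2 to 13.1 and 7.2 in replicate 1.

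The CMK response in total RNA differed between kin28is and WT for 23 genes, all with a more negative change in kin28is (blocked edgeR fit, 212 at unadjusted p under 0.05). Of these, 11 were on the Yap1 list, including GRE2 (-2.50 ± 0.464, adjusted p = 0.000361), HBN1 (-2.34), OYE2 (-2.07), the thioredoxin gene TRX2 (-1.82) and the thioredoxin reductase gene TRR1 (-1.73). HHF2 (-2.10) and HTB2 (-1.90) were the histone genes among them, and the cell wall gene GAS1 (-1.90), PSA1 (-2.15) and the glucose-6-phosphate dehydrogenase gene ZWF1 (-1.87) also differed. As lists, Yap1 (median -1.65; 11 of 24 called, 18 adjusted over the list alone) and histone genes (median -1.41; 2 of 10, 7 over the list alone) passed with adjusted p = 4.6e-28 and 3.8e-13, and each had adjusted p = 0.35 with an estimated correlation. Unblocked, edgeR called 0 genes (0 at unadjusted p under 0.05) and DESeq2 called 0. Relative scaling with the replicate term called 1. The fits that left out a library used S. pombe scaling and the replicate term. The count was 0 without WT DMSO replicate 1 or 2, 37 and 6 without WT CMK replicates 1 and 2, 77 without kin28is DMSO replicate 2, and 5 without kin28is CMK replicate 2. Without kin28is DMSO replicate 1 it was 64, of which 55 were higher and 9 lower.

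In the 5 µM set 1949 genes had a lower nascent than total change with CMK in kin28is cells and 1 a higher one. Every total RNA group had 1 library at that dose, so the fit held no spread between total RNA libraries. Its spread came from the nascent kin28is groups alone, and total RNA was assumed to vary like them. Across the numbers the nascent ratio to S. pombe, divided by the total ratio of the same group and number, changed by -0.90 and -1.64 log2 units with CMK. KIN28 fell by 2.19 in nascent RNA at 5 µM and stood at 0.09 in the blocked total RNA fit, which held both doses. It stood at 44.6 to 83.6 CPM over all total RNA libraries. The least-read S. cerevisiae genes stood at 49.2 RPKM in total kin28is CMK replicate 2 and at 3.02 in DMSO replicate 2. Total RNA changes of KIN28 and of other genes in this contrast were not separated from that background. With both doses edgeR called 0 genes (1 at unadjusted p under 0.05; DESeq2 0), and the same contrast for 1-NAPP-1 called 0 (0 at unadjusted p under 0.05; DESeq2 0).

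In kin28as cells with 1-NAPP-1 at 2 µM the nascent ratio to S. pombe was 4.16-fold and the total ratio 1.2-fold lower than with DMSO, with 1 library per group and no replicate check. In the same 2 µM set the nascent ratio with 1-NAPP-1 was 3.5-fold lower in WT cells, which have no sensitized kinase. Among genes, relative to the other S. cerevisiae genes, nascent ribosomal protein genes had a median of -0.50, ribosome biogenesis genes -0.50, G2/M genes -0.84 and glycolysis genes -0.69, all below nearly every one of 10000 matched random lists (percentiles 0, 0, 0 and 0.02). G1/S genes had a median of 0.35 (percentile 99.9) and other CTD kinases 0.44 (99.4). Yap1 genes did not stand apart in nascent RNA (median -0.24, percentile 32.5). In total RNA ribosomal protein genes stood at -1.0 (percentile 0), Yap1 genes at -0.82 (percentile 0.78, 22 of 24 below 0) and stress-induced genes at 0.32 (percentile 100). GRE2 stood at 3010 CPM with DMSO and 1162 with 1-NAPP-1. The 106 genes lowered by CMK in kin28is total RNA had a median of -0.97 here, with 103 of 106 below 0, while the central 95% of medians of matched random lists lay at -0.53 to -0.28. The least-read genes were at 5.35 with DMSO and 16.3 with 1-NAPP-1.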

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

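The tests of transcripts raised by 4tU, of a background common to barely transcribed genes, of carried-through RNA and of unequal S. pombe addition, and the counts over other splits of the libraries, were chosen after the results were seen.

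In nascent RNA the kin28is CMK library of replicate 1 stood apart from the 3 at 5 µM, with a log2 ratio to S. pombe of 3.80 against -0.96 or lower. Its gap to the nearest library was 0.843 of the whole range of the group, above Dixon's limit for 4 samples, in the only group large enough for this comparison, where chance passes the limit in about 1 of 20 groups. The replicate 1 libraries with DMSO (5.01) and in WT cells (5.48 with DMSO) were high too. The response to CMK differed between kin28is and WT cells for 23 genes in total RNA with the replicate term, led by GRE2 and HBN1, and for 18 genes in nascent RNA at 5 µM, led among the negative differences by OSI1 and HTB2. With the replicate term added to the 5 µM fit, which had 1 WT library per treatment, OSI1 stayed called and HTB2 did not. LTR entries, which entered no comparison, reached 476 CPM in total RNA of kin28is CMK replicate 2. They stood at 144 to 225 in the labelled DMSO libraries of WT and kin28is and at 406 in the library without 4tU. They were also above that DMSO range in WT cells of replicate 2, at 333 CPM with 1-NAPP-1 and 309 with CMK. The least-read S. cerevisiae genes were high in these same libraries. They stood at 49.2 RPKM in kin28is CMK replicate 2, 40.1 without 4tU, and 29.4 and 25.4 in WT with 1-NAPP-1 and CMK. The labelled DMSO libraries held 3.02 to 10.4. The LTR level was not separated from that background.

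The 106 genes lower in kin28is total RNA after CMK, led by Yap1 targets such as GRE2 and OSI1, had a median of -1.53 (quartiles -1.77 and -1.36) after removing a smooth trend on GC content and gene length, against -1.63 before. Subtracting reads spread evenly over the genome moved the median from -1.63 to -1.21 (quartiles -1.53 and -0.984), with 99.1% still called in a relative fit that called 1019 genes lower in all, so such reads may account for part of the fall and neither trend for the whole. Relative to the median gene, the same genes were higher in the labelled than in the unlabelled WT DMSO library, 106 of 106 above it. Their median stood at the 100 percentile of random lists, which were matched on expression and not on gene length. That CMK holds back transcripts that 4tU itself raises is a hypothesis. The comparison rests on 1 unlabelled library and was chosen with the genes in view. The percentile cannot decide it, because reads in the least-read genes were higher both without 4tU and with CMK. The 106 genes were also shorter than all tested genes (median 0.825 against 1.27 kb), so reads spread evenly by length add less to them. A loss of synthesis that shows first in short-lived transcripts stays open and was not tested.

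The 16 genes higher in kin28is total RNA after CMK, among them SDH9, MRX10, HFM1 and FLO11, kept a median of 2.78 after reads spread evenly by length were subtracted. That value decides nothing, although a bound of 1 had been set beforehand, because 13 of the 16 stood under 3 times the least-read genes in a kin28is DMSO or CMK library (a limit chosen after the result), where the fold after subtraction depends on the level subtracted. They may share a background common to barely transcribed genes: their multiple of the least-read genes moved by a median of 0.258 in replicate 1 and -0.199 in replicate 2, while their reads moved by 1.41 and 3.83 log2 units. Reads spread evenly and a response of the S. cerevisiae cells cannot be told apart from such a background. The 200 least-read genes of S. pombe, which met no inhibitor, rose 1.51-fold (95% interval 1.42 to 1.60) in replicate 1 and 5.79-fold in replicate 2, and the interval of the first spans the bound of 1.5 set beforehand.

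The fall of labelled RNA in kin28is cells with CMK was weighed against faults of the pull-down and of the S. pombe addition. Unlabelled RNA carried through adds S. cerevisiae reads, so an equal amount in each library shrinks the fall, and subtracting the ratio found without 4tU moved CMK minus DMSO from -1.21, -1.23 and -1.76 to -1.22, -1.53 and -2.12 log2 units in replicates 1 to 3. To make the fall, the DMSO library would have to carry more than the CMK library by at least 4.83 times that whole ratio, which was measured in 1 library. Unequal S. pombe addition would act on total RNA too if both fractions came from the same lysate, which is not given here. The nascent ratio divided by the total ratio still fell by 1.27 in the mean of 2 numbers (SD 0.526). That value cannot settle the question, and replicates 3 and 4 have no total RNA library. Lower synthesis of RNA in kin28is cells under CMK stays open as a hypothesis, as does a lower uptake of 4tU, and the ratio without 4tU equals 51.9% of the ratio in CMK replicate 4.

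Other splits of the same nascent kin28is libraries were fitted for the unblocked counts. Because the real splits gave 0 genes, every split gives as many, and these counts say nothing about chance. For CMK against DMSO the highest other of the 35 splits gave 5048 (35 of 35 as large). That split set DMSO replicate 2 and CMK replicates 2, 3 and 4 against the replicate 1 libraries and DMSO replicate 3, which points to the dose sets as a structure of the samples. With the replicate term the real comparison gave 1 gene and within the 5 µM set 3755. For CMK against 1-NAPP-1 the highest other of 35 gave 2, with 3902 genes within the 5 µM set. For 1-NAPP-1 against DMSO there were 10 splits, too few for a share under 0.05, with 0 genes in the real split and 0 in the highest other (10 of 10 as large).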

How the results depend on the processing

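The alternatives that subtract a background, add the replicate term to S. cerevisiae scaling or to the list tests, leave out nascent libraries with few S. cerevisiae reads (0 genes in 3 comparisons), or vary the blocked and the 5 µM fits were chosen after seeing the data, and all others before. Over 17 gene comparisons without a replicate term, which each gave 0 genes, 110 of 132 alternatives also gave 0, as did 104 of 107 fits that left out 1 library. The cause of the changes below was not tested, except that the 5 µM fits leave out the replicate 1 libraries. Where leaving out a library left an arm with 1 sample, that sample was assumed to vary like the other groups.

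Within the 5 µM set the nascent counts became 3755 for kin28is CMK against DMSO, 7 for 1-NAPP-1 against DMSO, 3902 for CMK against 1-NAPP-1, 4 for WT CMK, 4 for WT 1-NAPP-1, 18 for the CMK difference between kin28is and WT, 8 for the 1-NAPP-1 difference and 23 for kin28is against WT with DMSO. The nascent minus total contrast became 1950 for CMK and 4 for 1-NAPP-1 (HHT1, CMC1, RHO2 and ARO4). With the replicate term as a block, pairing libraries by number, nascent CMK gave 1 gene against DMSO and 1 against 1-NAPP-1 (HHT1 in both), and total RNA gave 122 for CMK against DMSO, 208 for CMK against 1-NAPP-1 and 23 for the CMK difference between kin28is and WT; the block changed no other gene count. S. cerevisiae scaling gave 1140 for total CMK against DMSO and 185 against 1-NAPP-1, and with the block 2025, 795 and, for the difference between kin28is and WT, 1 (YRO2). The same setting gave 4 for the CMK nascent minus total contrast (PIS1, PUP2, ESBP6 and CCS1). Fitting the compared groups alone gave 1 for total CMK against 1-NAPP-1 (ANB1). Genes named for these small counts were chosen after their values were seen.

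Around the blocked total RNA counts of 122, 208 and 23, other settings moved each in turn. Scaling by the plain S. pombe total gave 39, 85 and 8, S. cerevisiae scaling 2025, 795 and 1, DESeq2 256, 422 and 64, the compared groups alone 212, 1926 and 0, and subtraction of the evenly spread background with S. cerevisiae scaling 1788, 1332 and 285. Without the block all 3 were 0. Around the 5 µM counts, S. cerevisiae scaling gave 232 against 3755, 101 against 3902 and 0 against 18, and for the last the plain S. pombe total gave 28, DESeq2 1033 and the replicate block 5.

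Leaving out 1 library at a time, the unblocked counts ran from 0 to 4687 for nascent CMK against DMSO (4687 without CMK replicate 1), 0 to 232 for total CMK against DMSO and 0 to 1 for total kin28is against WT. The blocked counts ran from 16 to 1706 (1607 of these higher, without DMSO replicate 1), 26 to 96 and 0 to 77, and the 5 µM counts from 722 to 3901, 1560 to 4058 and 4 to 381. The log2 ratio to S. pombe kept its sign for nascent CMK against DMSO and for CMK against 1-NAPP-1 in kin28is, and otherwise reversed. In nascent RNA it ran from -1.68 to 0.688 for 1-NAPP-1 in kin28is, -1.70 to 1.92 for WT CMK, -2.63 to 0.982 for WT 1-NAPP-1 and -3.46 to 0.157 for kin28is against WT. In total RNA it ran from -1.02 to 1.12 for CMK, -0.76 to 1.38 for 1-NAPP-1 and -0.967 to 0.448 for CMK against 1-NAPP-1 in kin28is, from -0.539 to 0.967 for WT CMK, -0.627 to 0.88 for WT 1-NAPP-1 and -1.32 to 0.813 for kin28is against WT. These ratio differences are of unpaired means, so leaving out a library unbalances the 2 µM and 5 µM sets. Within same-number pairs total CMK against 1-NAPP-1 in kin28is differed by -0.25 and -0.27. Nascent WT CMK did so by 0.04 and 0.19, and nascent kin28is against WT with DMSO by -0.47 and -1.59. The other comparisons that reversed held both signs within pairs. Of the 144 list results 6 passed with an estimated correlation, 2 with the block and an estimated correlation, and 0 with S. cerevisiae scaling added. Depth limits the shallow nascent libraries most, with 517887 reads in kin28is 1-NAPP-1 replicate 2.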

Other observations

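The test of the list lowered by CMK against the labelled and unlabelled libraries was chosen after the result was seen. The percentiles of other lists and of the kin28as libraries in this part come from the same kind of random lists.

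Labelling itself went with a strong difference in total RNA of WT cells, between the labelled DMSO library of replicate 2 and the DMSO library without 4tU (1 library each, 5179 genes). GRE2 stood at 2294 CPM with 4tU and 62.3 without, HBN1 at 983 and 33.8, and OYE3 at 946 and 43.2. The 24 Yap1 genes had a median log2 difference of 2.88, with 22 of 24 above 0, at the 100 percentile of 10000 matched random lists. Heat shock genes were also high in the labelled library, with BTN2 at 5.04, HSP42 at 3.95, SSA4 at 3.71 and HSP82 at 3.25 log2 units, and the stress-induced list had a median of 1.27 (percentile 100). Glycolysis genes stood at 1.26 (percentile 100), TCA cycle genes at 0.72 (percentile 100) and Gcn4 amino acid genes at 0.84 (percentile 99.7). G1/S genes stood at -0.43 (percentile 0.01) and ribosome biogenesis genes at 0.32 (percentile 0.2), while histone genes were at 0.69 (percentile 79.6). The least-read genes were at 5.38 RPKM in the labelled library and 40.1 in the unlabelled one, so part of each difference moves with that background.

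The hypothesis that the transcripts lowered by CMK in kin28is are those raised by 4tU was tested on these 2 libraries. The 106 genes had a median labelled over unlabelled difference of 1.05, above all of the 10000 lists matched on expression (percentile 100). The central range of those lists was 0.589 to 0.81. They were not matched on gene length, and the 106 genes were shorter than all tested genes (median 0.825 against 1.27 kb). The least-read genes stood higher without 4tU than with it, and higher with CMK than with DMSO. A background shared by both comparisons was therefore not separated from a rise with 4tU. Of the 100 transcripts most raised by labelling, 31 were among the 106. BTN2, HSP42, SSA4 and HSP82 were raised by labelling without being called lower with CMK. In kin28as cells, where 1-NAPP-1 was the inhibitor, 103 of the 106 were below 0 in total RNA (median -0.97), where matched random lists also had medians below 0 (central range -0.53 to -0.28), and histone genes had a median of -0.33 (percentile 16.5). Whether the hypothesis extends to the histone genes, which CMK lowered in kin28is, cannot be told from their labelled over unlabelled percentile of 79.6. The 10 histone genes had a median of 0.687, with 9 above 0. The central range of random lists of that size was wide, at 0.0725 to 0.894.

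Some single genes in nascent RNA were far above their usual level in several libraries. CMC1 stood at 14830 CPM in kin28is 1-NAPP-1 replicate 2, 3556 in CMK replicate 2, 2813 in CMK replicate 3 and 2602 in WT DMSO replicate 2, against 81.94 in kin28is DMSO replicate 2. ARO4 stood at 8826, 1458, 1232 and 1547 in the same libraries and 114.8 in kin28is DMSO replicate 2. The nascent library without 4tU was also high, with CMC1 at 703, RHO2 at 504 and ARO4 at 519 CPM, against 81.94, 73.57 and 114.8 in kin28is DMSO replicate 2. HHT1 stood at 6019 in kin28is 1-NAPP-1 replicate 2 and 5951 in WT DMSO replicate 2, against 30.95 and 0 in CMK replicates 2 and 3. Whether amplification or a carried-over template set these levels cannot be read from counts.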
